A study of Mus musculus with 6 samples.

How the data were processed

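Gene expression was measured in total RNA from the colon mucosa of 6 mice, 3 control and 3 Dnmt3a-deleted, each hybridised to 1 Illumina mouse whole-genome bead array with a single biotin label. Per the labels' protocols, RNA was column purified, treated with DNase, checked on a Bioanalyser and amplified to biotinylated cRNA. The scanner, its software and the genome build were not given in the sources used here, so no coordinates are printed. Each sample carries its own animal number and was counted as 1 replicate.

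The deposited table of unprocessed values holds a mean signal intensity per probe on a linear scale, as scanned, with the background still in it, and beside each signal a deposited detection p-value. From the values, that p-value was 2-sided about the background level of each array: it was also small for probes dimmer than background, 6320 to 7410 of them per array at p under 0.05. The authors also deposited a table of processed intensities, which set against the unprocessed signals of the same arrays were linear, uncentred, with background left in, and matched between arrays by a method not given in the sources used here. The medians of its columns were 93.2, 93.3 and 92.9 for control replicates 1 to 3, and 93.3, 93.1 and 94.8 for Dnmt3a-deleted replicates 1 to 3. Array control probes, slides and scan dates were not used here.

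The main values were computed here from the unprocessed intensities with limma 3.58.1 in R 4.3.3. The planned method, neqc, takes background from a 1-sided detection p, and the 2-sided p ruled that out. Instead normexp background correction with parameters estimated from the intensities themselves (saddle-point method) and the same offset of 16 was followed by quantile normalization and log2. A probe counted as detected on an array when its p was under 0.05 and its signal lay above the array's background level, taken as the median signal of probes with p over 0.97. Probes detected on at least 3 of the 6 arrays were kept, 21183 of 45135. A gene was represented by its kept probe with the highest mean, and 4271 of the 11368 genes tested had more than 1 kept probe. Where no array of a group detected a gene, the fold is given as a bound, from the mean of the brighter group against the lowest detected value on each array of the dimmer group or the probe's own value, whichever was higher.

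Genes were named through the platform annotation: 34773 probes had 1 gene symbol, 18 had several and were left unnamed, and 10344 were not named here. Symbols were brought up to date by gene number for 34695 probes with a RefSeq gene table of assembly GRCm38.p6, used for names only, and 67 were kept as given. Of the kept probes, 3555 had no single gene name and entered only an alternative test of all kept probes.

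Groups were compared with limma's linear model and moderated statistics (lmFit, eBayes), 2-sided, over all 6 arrays with no covariate, at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are Dnmt3a-deleted minus control. Of 31 fixed gene lists, the 28 with at least 5 measured genes, the list of sex-linked genes left aside, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists. Camera was repeated with the correlation estimated from the data, where it also has only the residual degrees of freedom of the fit. Limma's fry, which tests a list against no change and not against other genes, was run on the same lists.

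The groups, the tests, the gene lists and the rule for the genes named were fixed before the data were examined. The rule took Dnmt3a and every measured gene of the DNA methylation machinery, 12 genes in each direction with non-overlapping groups (those past the threshold by fold, the remaining places by the smallest unadjusted p), and up to 4 genes of smallest p in each list. Genes with only a clone name were counted and not named, and 1 such gene was passed over among the higher genes. Genes named outside the rule are said to be so, and were chosen after their values were seen.

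Alternatives changed the background correction, the source of the normalized values, the normalization between arrays, the offset (50), the filter on dim probes, the probe rule, the variance moderation and the array weights, added the replicate number as a block, and left out each array in turn. After the data had been seen, sex as a term, the removal of Dnmt3a-deleted replicate 3, neqc with a 1-sided p, a 2-sided filter, an estimated correlation together with each other alternative, and a test of all kept probes were added. A fit with the slide as a block was not run.

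The fit was tested on simulated values for the Dnmt3a-deleted against control comparison, drawn for the 11368 genes with their own means and spread and with 200 genes changed. It recovered 42 of 100 genes changed 2-fold and 88 of 100 changed 4-fold, with 9 false calls and 0 of the wrong sign. With the spread measured without Dnmt3a-deleted replicate 3, it recovered 73 and 91. The simulated noise was independent between genes and of equal spread on all arrays, so no simulated array stood apart. The 200 planted changes also ease the adjusted threshold. These shares are therefore no measure of how many real changes the fit could miss. Simulated intensities with a planted log2 change of 2 gave a median estimate of 1.86 among bright probes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays, 3 per group, limits the precision.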

Results

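Expression was measured in colon mucosa of 5-month-old mice that carry the Min mutation of Apc, which predisposes to intestinal tumours, and 2 floxed alleles of Dnmt3a, a de novo DNA methyltransferase. The 3 Dnmt3a-deleted mice also carried a Cre transgene, named Fabp-Cre in the labels, which per the design removes the gene from 30 to 50% of mucosa cells, and the 3 control mice lacked it. A change confined to the deleted cells is therefore diluted by the other cells of the sample. Mean signal was 365, 360 and 379 on the arrays of control replicates 1 to 3, and 353, 368 and 285 on those of Dnmt3a-deleted replicates 1 to 3. Probes detected above background numbered 20970, 20783 and 21358, and 20685, 21296 and 19339, in the same order.

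Dnmt3a-deleted replicate 3 stood apart from the other 5 arrays. Its correlations with them over kept probes ran from 0.925 to 0.9496, while those among the other 5 were at least 0.978, and the first principal component, with 62.7% of the variance, placed it at 86.4 against -24.3 to 0.03 for the rest. Xist, the RNA that silences an X chromosome in females, and the Y-linked Eif2s3y showed that control replicate 1 was male and control replicates 2 and 3 female, and that Dnmt3a-deleted replicates 1 and 2 were male and replicate 3 female. The groups thus held 1 and 2 males, so values with sex as a term were also computed. The only female among the Dnmt3a-deleted mice was replicate 3, the array that stood apart. Within that group sex and this array cannot be told apart, and a sex term also takes up part of what sets the array apart.

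**Figure D1:**
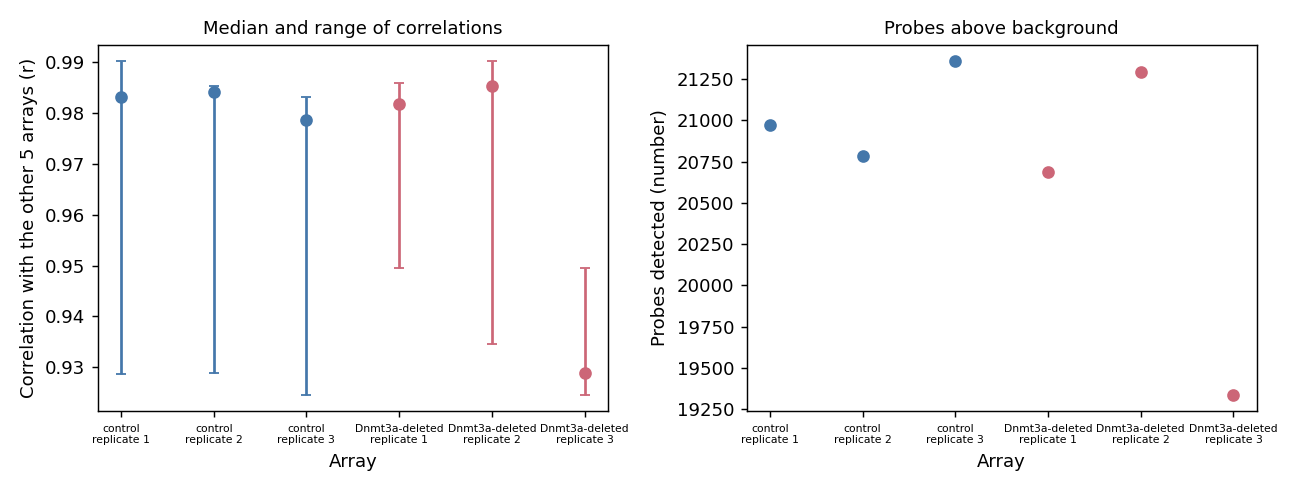
Left, Pearson correlation of log2 intensities of each array with the other 5 (point, median; bar, lowest to highest); right, number of probes detected on each array, on an axis that does not start at 0. Dnmt3a-deleted replicate 3 has the lowest median correlation, 0.929, and the fewest detected probes, 19339.

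The first question was whether the arrays register the deletion itself. None of the 3 Dnmt3a probes was detected above background on any array. Their mean log2 intensities were 4.62 ± 0.10, 4.89 ± 0.16 and 4.26 ± 0.01 in control and 4.59 ± 0.38, 4.68 ± 0.12 and 4.44 ± 0.19 in Dnmt3a-deleted mucosa (SD, n = 3), so no fold is given. Whether the probes lie in the deleted part is not known here, and the arrays neither bear out nor contradict the labels.

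The other DNA methylation genes were measured, and 0 of the 18 members of that list passed the test. Uhrf1, which brings the maintenance methyltransferase to replicating DNA, had a log2 difference of 0.57 ± 0.17 (SE), Dnmt3b, the other de novo methyltransferase, 0.54 ± 0.22, Dnmt1, the maintenance enzyme, 0.51 ± 0.23, Ehmt2 0.48 ± 0.23 and Trim28 0.36 ± 0.15, each with all 3 Dnmt3a-deleted values above the 3 control values and an adjusted p of 0.701. Dnmt3b, Dnmt1 and Ehmt2 stood at 7.74, 9.01 and 10.49 in Dnmt3a-deleted replicate 3. They stood at 7.12, 8.37 and 9.80 in replicate 1 and at 6.97, 8.14 and 9.75 in replicate 2. A large part of their mean differences thus came from the array that stood apart. Uhrf1 (10.14, 10.29 and 10.43 in replicates 1 to 3) and Trim28 (10.75, 10.92 and 10.75) varied less between these mice. Values for Uhrf2, Zbtb38, Tet3, Mbd3, Mbd4, Setdb1 and Mbd2 were 0.41, 0.28, 0.22, 0.21, 0.21, 0.15 and 0.07. Those for Cxxc1, Zbtb33, Gadd45b, Mbd1, Tdg and Gadd45a were -0.09, -0.19, -0.24, -0.34, -0.34 and -0.88. The sign turned for Setdb1 with median scaling, for Mbd2 with median scaling, loess, the authors' values and array weights, and for Uhrf2 with the mean of its probes (-0.32). Without Dnmt3a-deleted replicate 3 it turned for Mbd2, Zbtb38, Cxxc1 and Tdg, and for Mbd3 when sex was a term as well, and with array weights for Zbtb38 and Cxxc1. Mbd2 also turned without control replicate 1 or 2. As a list these genes had a median of 0.21 and an adjusted camera p of 0.241. The list passed in 1 alternative, with sex as a term and Dnmt3a-deleted replicate 3 left out (mean 0.15, adjusted p 0.0444, and adjusted p = 0.755 with an estimated correlation).

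The second question was which genes differ between Dnmt3a-deleted and control mucosa. Tff2, a secreted trefoil peptide of mucus, was the 1 gene of 11368 to rise past the threshold. Its log2 intensity was 5.67 ± 0.30 in control and 9.73 ± 0.42 in Dnmt3a-deleted mucosa (SD, n = 3), a difference of 4.06 ± 0.25 (SE) or 16.7-fold, with an adjusted p of 0.00362 by limma. Single values were 5.91, 5.77 and 5.33 against 9.98, 9.97 and 9.26. Tff2 has 1 probe on the array, detected on all 6. The size depended on the processing, with log2 changes of 3.04 from the authors' values (adjusted p 0.0466) and 3.06 without background correction (adjusted p 0.0479), and adjusted p ran from 4.31e-06 to 0.0562 over all alternatives. The call held without Dnmt3a-deleted replicate 3 (4.30, adjusted p 0.000690) and with sex as a term (3.89, adjusted p 0.00124), and was lost without control replicate 2 (4.12, adjusted p 0.0562). Hoxb6 and Osr2, of the list on position along the colon, stood -2.55 and -2.09 from the control mean in Dnmt3a-deleted replicate 1, -0.30 and 0.24 in replicate 2 and -2.46 and -3.71 in replicate 3.

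Among genes that did not pass, the smallest p-values of the higher group included Tpm2, a tropomyosin of contractile filaments, at 7.53 ± 0.21 against 5.47 ± 0.59 (log2 2.06, adjusted p 0.477), detected on 1 of 3 control arrays. Ang4, an antimicrobial ribonuclease of goblet and Paneth cells, had the widest difference of these genes, 4.38 ± 1.02 (SE), with values of 11.72, 9.14 and 12.17 against 8.71, 5.37 and 5.81. Crip2 stood at 1.53, Ntn5 at 0.98, the tuft cell gene Sh2d6 at 0.97, Pcdh17 at 0.93, the replication factor Cdc45 at 0.78, Sgsm1 at 0.77, the iron transporter Slc11a2 at 0.76 and Aunip at 0.67. Kcne1l was not detected in control mucosa and was at least 1.52-fold higher in Dnmt3a-deleted mucosa. Adjusted p was 0.701 for each of these except Tpm2.

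On the lower side 0 genes passed by limma. Among the smallest p-values was that of Klrd1, a receptor chain of NK cells and some T cells, at 5.93 ± 0.24 against 7.42 ± 0.29 (SD, n = 3; log2 -1.50, adjusted p 0.477). The T cell receptor genes Cd3e and Trgv5 had differences of -1.08 and -1.10, the Fc receptor chain Fcer1g -1.20, the leukocyte genes Sla, Arhgdib and Cd52 -1.35, -0.997 and -0.871, and the inflammatory signals Cxcl2 and Il1b -2.39 and -2.32, all at an adjusted p of 0.701. Trgv5, Cxcl2 and Hoxd4 were each detected on 1 Dnmt3a-deleted array. Hoxd4 (-1.11) and Sult1c2 (-0.82) had the same adjusted p, as did Zc2hc1c, which was not detected in Dnmt3a-deleted mucosa and was at least 1.30-fold lower there. At an unadjusted p under 0.05 there were 352 higher and 245 lower genes, 597 in all, where 568.4 are expected by chance. That number ran with the setting: over the same genes it was 318 without control replicate 1, 1344 without Dnmt3a-deleted replicate 2, 1652 with sex as a term and 2215 with array weights. The balance of directions did too, at 280 higher and 282 lower with loess and 197 and 308 with median scaling. The groups did not overlap for 1651 genes, 14.5% against the 10% that chance gives for a single gene. Genes vary together and the share was not computed for other splits of the samples, so no excess can be read from it.

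**Figure D2:**
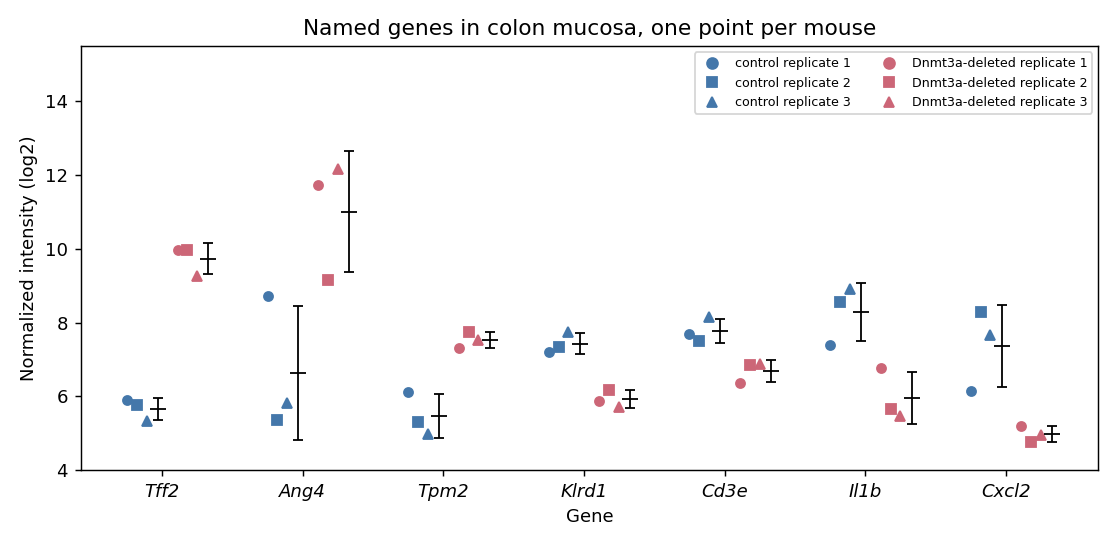
Normalized log2 intensity of 7 genes in each of the 6 mice; points are mice, and black bars give the group mean ± SD (n = 3). Tff2 separates the groups by 4.06 with an adjusted p of 0.00362, and the other 6 genes did not pass the test.

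Array weights, estimated from the same 6 arrays, were 6.04, 0.809 and 0.154 for Dnmt3a-deleted replicates 1 to 3. Most of that group's weight thus lay on a single mouse. With these weights the counts were 7 higher and 8 lower. Klrd1, Cd3e, Arhgdib, Cd52, Hoxd4 and Zc2hc1c were among the lower genes, and Sh2d6, Kcne1l, Crip2, Tpm2 and Cdc45 among the higher ones. Leaving out Dnmt3a-deleted replicate 3 gave 1 higher and 0 lower.

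The third question was whether groups of genes moved together. Of 28 lists tested, 8 passed camera with the preset correlation, 7 of them lower and 1 higher in Dnmt3a-deleted mucosa. With an estimated correlation 0 passed, the smallest adjusted p being 0.437, and 0 passed by fry, the smallest being 0.249. All 8 calls thus rest on the preset correlation. Without Dnmt3a-deleted replicate 3, or with sex as a term, 9 and 7 lists passed, and 0 in either with an estimated correlation (smallest adjusted p 0.517 and 0.513). Calls that other alternatives added are given with each list, those with the replicate number as a block aside, and with an estimated correlation 0 lists passed in any of them by camera (smallest adjusted p from 0.327, with no filter on dim probes, to 0.755).

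T cell and NK cell markers fell furthest by this test, with a median log2 change of -0.65 over 16 measured genes and an adjusted p of 7.38e-10 (adjusted p = 0.437 with an estimated correlation). Of these genes 14 were lower, 10 of them at an unadjusted p under 0.05. Adjusted over the list alone 10 passed, and over all genes tested 0 did. The chemokine Ccl5 had a difference of -2.05 ± 0.57 (SE), Nkg7, a granule protein of cytotoxic cells, -1.23 ± 0.34, and Cd3g, outside the naming rule and chosen after its value was seen, -1.43. Cd8b1, likewise chosen, was at 0.43. The list mean relative to the 6 arrays was 0.19, 0.13 and 0.72 in control and -0.54, -0.10 and -0.40 in Dnmt3a-deleted mucosa. Of the macrophage, granulocyte and mast cell markers, 8 of 14 were lower, with Fcer1g at -1.20 and Tyrobp, an adaptor of myeloid and NK receptors that was not detected in Dnmt3a-deleted mucosa, at least 1.46-fold lower (list adjusted p 0.0529). Adjusted over the list alone 2 of them passed, and over all genes 0. Lyz2 was at -0.80, and Aif1 went the other way, at 0.43. The median of the list was -0.06, and 5e-04 without Dnmt3a-deleted replicate 3. The list passed without control replicate 1 (mean -0.27, against -0.18 over all arrays, adjusted p 0.00342), without Dnmt3a-deleted replicate 1 (0.0386) and with no filter on dim probes (0.0140). The adjusted p of these was 0.428, 0.629 and 0.327 with an estimated correlation. B cell and plasma cell markers were lower in 6 of 6 genes with a median of -0.13 (adjusted p 0.0660), and passed without control replicate 2 (mean -0.29, adjusted p 0.0179, and adjusted p = 0.455 with an estimated correlation) and with no filter on dim probes (0.0271, and adjusted p = 0.545 with an estimated correlation).

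Antimicrobial and epithelial inflammatory genes fell with a median of -0.53 over 28 genes, 18 of them lower (adjusted p 0.00282, and adjusted p = 0.437 with an estimated correlation). Beside Il1b and Cxcl2, which were adjusted over the list alone the 2 that passed, the acute phase gene Saa3 had a difference of -1.16 ± 0.41 (SE). Sprr2a1 went the other way, at 0.50 ± 0.17 (SE), with all 3 Dnmt3a-deleted values above the control values. Without Dnmt3a-deleted replicate 3 the median was -0.30 (adjusted p 0.0210), and with array weights the list did not pass (mean -0.37 against -0.60, adjusted p 0.0912). Some falls came from 1 control mouse, in genes outside the naming rule and chosen after their values were seen. Tnf, Cxcl1 and Tnfaip3 were at 10.03, 11.24 and 10.85 in control replicate 3 and at most 7.33, 7.39 and 7.96 elsewhere. Lcn2 was at 8.69 in control replicate 2 and at most 6.36 elsewhere. The list mean relative to the 6 arrays was 0.15, 0.28 and 0.48 in control and -0.08, -0.34 and -0.49 in Dnmt3a-deleted mucosa. Interferon and antigen presentation genes fell with a median of -0.27, 27 of 35 being lower (adjusted p 9.21e-04, and adjusted p = 0.484 with an estimated correlation). Rsad2, an antiviral protein, was at -0.71 and the immunoproteasome subunit Psmb8 at -1.06 in that list, with 0 genes at an unadjusted p under 0.05, and 0 adjusted over the list alone. Psmb8 was at 9.89 in Dnmt3a-deleted replicate 3 and at 12.17 or above on the other arrays. Without that replicate the list had a median of -0.07 and an adjusted p of 0.0530 (0.0565 if left out before normalization, and 0.765 with sex as a term as well). Without control replicate 3 the list had a mean of -0.17 and an adjusted p of 0.0619. Without Dnmt3a-deleted replicate 2 its mean was -0.47, against -0.27 over all arrays (adjusted p 1.17e-06, and adjusted p = 0.521 with an estimated correlation).

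Genes of fatty acid oxidation and PPAR targets fell with a median of -0.52, 20 of 24 being lower (adjusted p 1.17e-05, and adjusted p = 0.437 with an estimated correlation). The lipid droplet proteins Plin2 and Cidec were at -0.58 and -0.98, and Hadhb, a subunit of the mitochondrial trifunctional protein, at -0.50. Xenobiotic metabolism genes fell with a median of -0.44, 19 of 26 being lower (adjusted p 2.29e-04, and adjusted p = 0.437 with an estimated correlation), with the sulfotransferase Sult1d1 at -1.32 ± 0.32 (SE) and the cytochrome P450 Cyp2c65 at -2.04 ± 0.89. Ugt2b34 was at -0.67, and Gstm2 went the other way, at 0.45, with all 3 Dnmt3a-deleted values above the control values. The array that stands apart had the lowest mean of both lists, -0.78 and -0.68, and without it the medians were -0.29 and -0.20 (adjusted p 6.50e-04 and 0.00706). Dnmt3a-deleted replicate 1 stood at -0.14 and -0.24, below the control mice. Replicate 2 stood at 0.16 and 0.22, within the control ranges of 0.13 to 0.42 and -0.05 to 0.49. Adjusted over the list alone 0 genes of either passed.

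Tuft cell markers rose with a median of 0.24, 12 of 14 being higher (adjusted p 0.00140, and adjusted p = 0.437 with an estimated correlation). Beside Sh2d6, the actin-binding protein Avil was at 0.87 ± 0.23 (SE), Ltc4s, which makes leukotriene C, at 0.67 ± 0.22 and the cation channel Trpm5 at 0.62 ± 0.20. The list mean of 0.34 was 0.16 with the authors' values, 0.17 without background correction and 0.22 with the higher offset, where the list still passed (adjusted p 0.00719, 0.00740 and 0.00502). Adjusted over the list alone 2 passed, and over all genes 0. Immediate early and heat shock genes fell with a median of -0.25, 17 of 22 being lower (adjusted p 0.0303, and adjusted p = 0.533 with an estimated correlation). In that list Egr2 was at -1.19, Hspa1b at -1.11 and Dusp1 at -0.42, while Ier2 went the other way, at 0.68. That list stood at 0.81 in control replicate 3 and from -0.45 to 0.40 on the other arrays. Its call was lost with sex as a term (mean -0.09, adjusted p 0.383) and with Dnmt3a-deleted replicate 3 also left out (mean -0.39, adjusted p 0.0732). It was also lost with median scaling (mean -0.29, adjusted p 0.135) and without Dnmt3a-deleted replicate 1 or 2 (means -0.14 and -0.09, adjusted p 0.213 and 0.282). The direction turned without control replicate 3, to a mean of 0.10. The change was larger without Dnmt3a-deleted replicate 3 (median -0.45, mean -0.51 against -0.24 over all arrays, adjusted p 5.72e-05, and adjusted p = 0.517 with an estimated correlation), without control replicate 2 (mean -0.53, adjusted p 6.55e-05, and adjusted p = 0.526 with an estimated correlation) and with array weights (mean -0.38, adjusted p 0.00152, and adjusted p = 0.493 with an estimated correlation). Genes of p53 targets and apoptosis fell with a median of -0.21, 16 of 20 being lower (adjusted p 0.0370, and adjusted p = 0.437 with an estimated correlation). That call was lost without control replicate 3 or without Dnmt3a-deleted replicate 2 or 3 (adjusted p 0.104, 0.136 and 0.0744), with sex as a term (0.114), with Dnmt3a-deleted replicate 3 left out before normalization or together with sex as a term (0.0565 and 0.511), with array weights (0.283) and with the stricter filter on dim probes (0.0659). The list mean of -0.16 stayed at -0.15 without Dnmt3a-deleted replicate 3. It was -0.09 without control replicate 3, -0.08 with array weights, -0.05 with sex as a term and Dnmt3a-deleted replicate 3 left out, and -0.26 with median scaling. Apaf1, with the smallest p of the p53 list, went the other way, at 0.57. Trp53inp1, Sesn2 and Bcl2 were at -0.44, -0.35 and -0.61. Adjusted over the list alone 0 genes of either list passed.

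**Figure D3:**
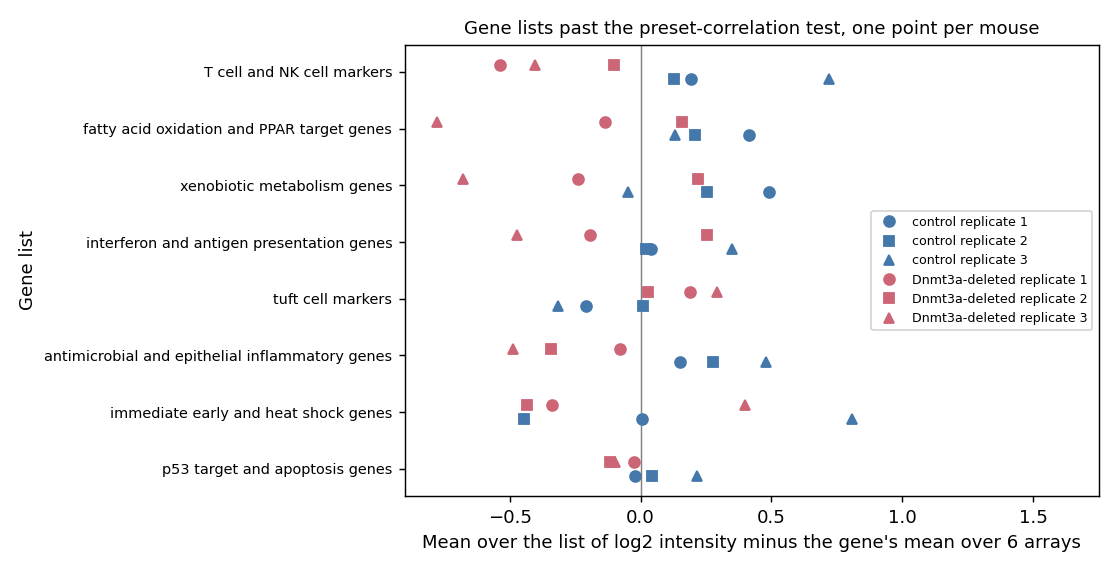
Mean over each of 8 gene lists of the log2 intensity minus the gene's mean over the 6 arrays; points are mice. T cell and NK cell markers lie at 0.13 or above in the 3 control mice and at -0.10 or below in the 3 Dnmt3a-deleted mice. The groups overlap for immediate early, interferon and antigen presentation, fatty acid oxidation and xenobiotic metabolism genes.

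The remaining 20 lists did not pass, with adjusted p from 0.0529 to 0.957. Genes reported silenced by promoter methylation in colorectal cancer had a median of -0.01 and a mean of 0.06 over 27 genes, 13 higher and 14 lower, and the test against all other genes pointed down (adjusted p 0.834) but up with loess or median scaling. Adjusted over the list alone 1 of them passed, as did 1 smooth muscle gene and 1 gene of the list on position along the colon. Pcdh17, a protocadherin, and Cdkn1c, a cyclin-dependent kinase inhibitor that is also imprinted, had differences of 0.93 and 1.30, and Wif1, a secreted Wnt inhibitor, -0.34. Imprinted genes had a median of 0.14, with Phlda2 at 0.58 (adjusted p 0.0781). The list passed with the mean of a gene's probes (list mean 0.33, adjusted p 0.0248), without control replicate 1 (0.32, adjusted p 0.0288) and with the filter on either side of background (0.26, adjusted p 0.0381). Their adjusted p was 0.464, 0.467 and 0.478 with an estimated correlation. Wnt/beta-catenin targets had a median of 0.12 (adjusted p 0.519), with Axin2 at 0.52, Ccnd1 at 0.45 and Tiam1 at 0.42. Intestinal stem cell markers had a median of 0.03, a mean of -0.08 and a test pointing down (adjusted p 0.469), with Prom1 at -1.29.

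Goblet cell markers had a median of 0.19, 18 of 25 being higher (adjusted p 0.0660), with Clca1, a secreted mucus protein, at 1.68 ± 0.42 (SE). The list passed without Dnmt3a-deleted replicate 3 (adjusted p 0.0316, and adjusted p = 0.556 with an estimated correlation), without control replicate 1 or 2 (0.0111 and 0.00561), with median scaling (0.0192), with no filter on dim probes (0.0207) and with the filter on either side of background (0.0425). Adjusted p for these calls ran from 0.509 to 0.576 with an estimated correlation. Absorptive colonocyte markers had a median of -0.11 (adjusted p 0.0616), with the chloride exchanger Slc26a3 at 1.14. Without Dnmt3a-deleted replicate 3 their median was 0.03 (adjusted p 0.997), while the list passed with sex as a term (adjusted p 0.00280, and adjusted p = 0.513 with an estimated correlation) and without control replicate 3 or Dnmt3a-deleted replicate 1 or 2 (0.00611, 0.0294 and 0.00909), and with the mean of a gene's probes (0.0392). With an estimated correlation the adjusted p of the last 4 was 0.421, 0.629, 0.541 and 0.527. The enteroendocrine hormones Insl5 and Sst had opposite signs, 1.14 and -0.95. Cell cycle genes had a median of 0.11, 20 of 29 being higher (adjusted p 0.0818), with Cdc20 at 0.81, Plk1 at 0.67 and Mcm2 at 0.46. Without Dnmt3a-deleted replicate 3 this list passed, with a median of 0.23 and an adjusted p of 5.72e-05 (adjusted p = 0.517 with an estimated correlation), and it also passed without control replicate 1 or 3 (0.0360 and 0.0172), with array weights (0.0106), with the mean of a gene's probes (0.0392) and with Dnmt3a-deleted replicate 3 left out before normalization or together with sex as a term (6.42e-05 and 0.0227). For these calls adjusted p ran from 0.418 to 0.755 with an estimated correlation. Fibroblast, smooth muscle and endothelial lists had medians of -0.02, 0.09 and 0.05 (adjusted p 0.531, 0.465 and 0.957), and for the endothelial list the test pointed down while the mean was 0.11. Lists of enteroendocrine, circadian clock, cholesterol synthesis, unfolded protein response and fat cell genes had adjusted p of 0.400, 0.0781, 0.176, 0.0719 and 0.170. Cholesterol synthesis genes passed, with means above 0, without Dnmt3a-deleted replicate 3 (adjusted p 0.0114, and adjusted p = 0.517 with an estimated correlation), also before normalization or with sex as a term (0.0122 and 0.0138), without control replicate 3 (0.0172) and with array weights (0.00389). With means below 0, circadian clock genes passed without control replicate 1 or Dnmt3a-deleted replicate 1 (0.0280 and 0.0386), and fat cell genes with array weights and with sex as a term and Dnmt3a-deleted replicate 3 left out (0.0164 and 0.0109). Unfolded protein response genes, also with means below 0, passed without control replicate 1 or 2 or Dnmt3a-deleted replicate 2 (0.00829, 0.0282 and 0.0289) and with the mean of a gene's probes (0.0382). With an estimated correlation the calls of these 4 lists had an adjusted p of 0.355 or more. Germline genes kept silent by methylation had 2 measured members and enteric neuron and glia markers 3, too few for the test.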

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

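Sex as a term, the removal of Dnmt3a-deleted replicate 3 with it or before normalization, neqc with a 1-sided p, the filter on either side of background, the estimated correlation joined to any other alternative, and the test of all kept probes were chosen after the result was seen. Tff2 was called under every alternative except without control replicate 2 (log2 4.12, adjusted p 0.0562), with log2 changes from 3.04 (the authors' values) to 4.54 (neqc) and adjusted p from 4.31e-06 to 0.0562. The number of higher genes was 7 with array weights and 0 to 1 with each array left out in turn, and of lower genes 8 with array weights, 0 with each array left out, and 1, Apoa1, with sex as a term and Dnmt3a-deleted replicate 3 left out. The number of lists was 0 with an estimated correlation, alone or joined to each other alternative in which lists were tested by camera, 0 by fry, 8 to 14 with each array left out (14 without control replicate 1), and 7 to 12 otherwise. These changes, and the turns of direction below, have causes that were not tested. Dim probes limit what can be said of genes such as Dnmt3a, whose signal does not rise above background.

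Same-numbered samples are different animals, and their deviations from the group means correlated at -0.13, -0.10 and 0.03, so they were not treated as pairs. With the replicate number as a block, 1 gene was higher and 0 lower, 10 lists passed, with absorptive colonocyte and circadian clock genes added (adjusted p 0.0214 and 0.0406, each 0.533 with an estimated correlation), and Tff2 had an adjusted p of 0.00645. The slide as a block was not run.

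Directions that turned belonged to genes and lists that had not passed, except that of immediate early genes. Mbd2 was at -0.0048 with the authors' values, -0.0117 with loess, -0.0811 with median scaling, -0.0845 with array weights, -0.0620 with sex as a term and Dnmt3a-deleted replicate 3 left out, and -0.23 with it left out before normalization. In the last 2 settings Cxxc1 was at 0.32 and 0.19, Tdg at 0.0551 and 0.0021, Zbtb38 at -0.0011 and -0.0765, and Fxyd4 at 2.24 and 0.17. In the former alone Mbd3 was at -0.0139, Rsad2 at 0.0219 and Defa20 at -0.58. With array weights Cxxc1 was at 0.26, Zbtb38 at -0.0118, Fxyd4 at 0.89 and Defa20 at -1.37. With sex as a term Fxyd4 was at 0.41 and Defa20 at -0.13. Setdb1 was at -0.0141 with median scaling, Uhrf2 at -0.32 with the mean of its probes, and Fxyd4 at 0.16 with neqc. With each array left out Mbd2 ran from -0.22 to 0.40, Cxxc1 from -0.26 to 0.19, Tdg from -0.52 to 0.0023, Zbtb38 from -0.0726 to 0.46, Fxyd4 from -1.08 to 1.94, Apoa1 from -1.83 to 0.71 and Defa20 from -1.06 to 1.752.

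For lists, a turn is one of camera's direction against all other genes, and the list mean is given. The mean of silenced genes was 0.0439 with loess, -5e-04 with median scaling, 0.17 with the strict filter, 0.0934 with sex as a term and 0.0678 with sex and Dnmt3a-deleted replicate 3 left out. In the last 2 settings fibroblast genes were at 0.0851 and 0.10, and they were at 0.0239 with no filter and 0.0720 with the filter on either side. Endothelial markers were at 0.10 with no filter, 0.15 with array weights, 0.11 with the block, 0.22 with sex as a term and 0.15 with neqc. Smooth muscle markers were at -0.0089 with the strict filter and 0.0663 with array weights, stem cell markers at 7e-04 with no filter, and position genes at 0.16 with array weights and 0.20 with sex as a term and Dnmt3a-deleted replicate 3 left out, where unfolded protein response genes were at 0.0971. Fry, which tests a list against no change and not against other genes, pointed up for silenced, fibroblast and endothelial genes (means 0.0603, -0.0328 and 0.11 over all 6 samples) where camera pointed down, the answer to a different question and no turn. With each array left out, immediate early genes ran from -0.53 to 0.10, silenced genes from 0.0186 to 0.10, fibroblast genes from -0.16 to 0.0478, endothelial markers from -0.0318 to 0.28, and small intestine and pancreas genes from -0.41 to 0.0881.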

Other observations

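All tests weighed here except those of other splits of the samples and of T and NK genes outside the fixed list were chosen after the result was seen, and the genes named here, Tff2 and Ang4 aside, were picked for their values unless the naming rule also took them. Dnmt3a-deleted replicates 1 and 3 had low levels of several genes that replicate 2 did not. The homeobox genes Hoxb6 and Hoxb7, the transcription factor Osr2 and the cytochrome P450 Cyp2c65 had log2 intensities of 5.21, 6.70, 9.96 and 9.91 in replicate 1 and 5.30, 6.48, 8.34 and 7.95 in replicate 3. In replicate 2 they stood at 7.46, 9.42, 12.29 and 12.13, near the control means of 7.76, 9.71, 12.05 and 12.04. Ang4 and the pentraxin Mptx1 went the other way: Mptx1 was at 12.65 and 13.31 in replicates 1 and 3, 11.09 in replicate 2 and 10.38 to 10.54 in control. No gene of these passed the test between groups.

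Some genes varied as widely within the control mice. Fxyd4, a regulator of the sodium pump, ran from 5.67 to 11.70 among the 3 controls. Apoa1, an apolipoprotein of the small intestine, was at 9.63 in control replicate 1 and at most 5.60 on any other array. Defa20, a Paneth cell defensin, was at 8.002 in control replicate 1, 10.23 in Dnmt3a-deleted replicate 2 and at most 5.48 elsewhere. The lists of position along the colon (median -0.06, mean 0.04, adjusted p 0.339) and of small intestine and pancreas genes (median -0.25, adjusted p 0.0818) did not pass. The latter passed, lower in Dnmt3a-deleted mucosa, without control replicate 3 (mean -0.41, adjusted p 0.00611), with array weights (-0.52, adjusted p 0.00620) and with sex as a term and Dnmt3a-deleted replicate 3 left out (-0.73, adjusted p 1.50e-06), and its mean was 0.0881 without control replicate 1. With an estimated correlation the adjusted p of these 3 calls was 0.355, 0.368 and 0.755.

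Dnmt3a-deleted replicate 3 stood apart from the other 5 arrays. Lower signal that leaves dim probes noisy is argued against as the whole cause, since among the brightest probes, above the 0.75 quantile of mean signal, its spread was still 2.29 times the largest of the other arrays. RNA loss or breakage is a candidate explanation: over 972 genes with 2 bright probes, the spread of the difference between both probes was 4.12 times the largest elsewhere, although changes in isoform could move probes apart too. A stronger effect of the deletion in this animal stays open, since its change correlated across genes at 0.334 with that of Dnmt3a-deleted replicate 1 and at 0.0525 with that of replicate 2, and those of replicates 1 and 2 at 0.0629 with each other, with no control shared, and animals may differ in the share of cells deleted. The bound for this test was widened after the value was seen, from a low correlation with either replicate to one with both.

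T cell and NK cell markers were lower in Dnmt3a-deleted mucosa by camera with the preset correlation, a call lost with an estimated one (adjusted p = 0.437 with an estimated correlation) and by fry (adjusted p 0.249), so whether the list moved at all stays open. Taken singly, neither the array that stands apart nor the unequal numbers of males and females accounts for the lower mean. It was -0.66 without that array and -0.67 with sex as a term, against -0.69 in all 6 samples. That array is the only female of its group, so the sex term is not free of it. Among males the list had a mean level of 7.19 in control replicate 1 and 6.47 and 6.90 in Dnmt3a-deleted replicates 1 and 2. Among females it was 7.13 and 7.72 in control replicates 2 and 3 and 6.60 in Dnmt3a-deleted replicate 3. Control replicate 3 had the highest level of the 6 arrays. With each array left out in turn, the mean change of the list ran from -0.82 to -0.51. Fewer T and NK cells would lower T and NK genes outside the list as well. A set of 19 such genes was fixed before their values were seen. It replaced a first test on members of the list itself, which would have counted for fewer cells. The 19 genes had a mean of -0.12 with an SD over genes of 0.60 and a median of -0.20. Without Dnmt3a-deleted replicate 3 their mean was -0.22 (SD 0.38), and each value lay between the bounds set in advance. The 19 genes were dimmer than the list, and the offset shrinks changes of dim genes. Their mean levels in control replicates 1 to 3 were 6.02, 5.91 and 6.39, against 7.19, 7.13 and 7.72 for the list. Of the 19 genes 14 were lower, among them Ctsw at -0.92. Prf1, the perforin of cytotoxic cells, was at 1.82, with 11.23 in Dnmt3a-deleted replicate 3 and 7.65 and 7.78 in replicates 1 and 2. Fewer of these cells therefore stays an open hypothesis, as does lower expression within them.

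Tff2 was higher in all 3 Dnmt3a-deleted samples, and sex is argued against by the log2 change of 3.89 with sex as a term. The change was 4.07 when Dnmt3a-deleted replicate 3, the only female of its group, was also left out. Position along the colon stays open: of 13 position genes the groups did not overlap for 1, Ang4 (7.69%, where chance gives 10%), but 3, Hoxb6, Osr2 and Ang4, lay over 1 on the log2 scale outside the control range in Dnmt3a-deleted replicates 1 and 3. In replicate 2, where Tff2 was as high as in replicate 1, Hoxb6 and Osr2 were near the control mean, but that is a single array, and both an earlier test and the bound of this one were changed after the values were seen. Stomach tissue is argued against by 0 of 8 gastric genes being detected on all 3 Dnmt3a-deleted arrays and over 2-fold higher. Gkn1, Gkn2, Pgc and Muc6 were at 4.97, 4.76, 4.71 and 4.58 there. A Muc5ac probe and Cblif, each detected on 5 arrays, were however at 5.83 and 5.24 against 5.51 and 5.31 in control. Duodenal gland tissue stays open, because the set was one of gastric genes and the Muc6 probe was detected on 0 arrays. An effect of the Dnmt3a deletion on Tff2 stays an untested hypothesis, since no methylation was measured and the Cre transgene, present only in these mice, was not separated from the deletion.

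Only 10 splits of the 6 samples into 3 and 3 exist, too few for a share under 0.05. The real split called 1 gene and the highest of the others 2, so 2 of the 10 splits gave as many genes. That other split parted males from females and called Eif2s3y and Xist, and the remaining 8 called 0 genes by limma, with 187 to 782 at an unadjusted p under 0.05. With sex as a term the real split called 1 gene. For lists the real split called 8 and the highest of the others 8, so 2 of 10 gave as many. Each of the other splits called at least 1 list with the preset correlation.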
